A study of Mus musculus with 12 samples.

How the data were processed

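RNA was measured in 12 libraries of sorted mouse muscle progenitors, 3 in each of 4 groups set by genotype and load. Per the labels' protocols, 1000 Pdgfra-positive cells were sorted into each tube of lysis buffer, and libraries followed a published low-input protocol that tags 3′ ends (CEL-Seq2). The authors deposited a table of raw counts per gene, with whole numbers that sum to a different total in each library. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.26.0 with the mouse build GRCm38. The annotation release, the strand setting, the use of molecular identifiers, the time between surgery and sampling, the floxed exons and the pooling of animals are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart. Reads of near-identical genes, such as the haemoglobin alpha copies, class I histocompatibility genes, and Gapdh and ribosomal protein genes with their pseudogenes, may be split or lost in counting, so their values are uncertain.

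Gene names, biotypes and coordinates came from the GRCm38 annotation by gene identifier, and 54100 of 54100 identifiers matched. No column of the table was left out. Samples were mapped to groups and replicate numbers from their labels. Library totals ran from 336437 to 1564581 counts, so a floor of 3 counts corresponds to between 1.95 and 9.72 CPM. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 3.22 to 19.2 over genes), so no pair was treated as a single library. Counting intervals and floors cover counting error only, since reads are not independent molecules where identifiers are not used.

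Tests used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr, libraries were scaled by TMM factors, and 1 robust quasi-likelihood model with a mean per group was fitted to all 12 libraries, so that the groups share an estimate of the spread. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over 8161 genes, and standard errors are the absolute log2 fold change divided by the square root of F. Tests are two-sided. The 5 contrasts were overload against sham in each genotype, cdKO against control under each load, and the interaction. A fitted fold change against a group with no counts depends on the prior count of 2, so such genes are given as bounds against 3 counts per library, and those with 1 to 3 counts as ratios with exact 95% counting intervals.

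The 37 gene lists, fixed by name, cover processes and cell type markers that fit this tissue, and each is named where its result is given. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Lists with at least 3 tested members (34 of 37) were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 170 tests (34 lists in 5 comparisons). Of these tests 81 passed, and 0 of the 81 did with an estimated correlation. fry, which asks only whether the genes of a list move on balance one way, was an alternative. The genes named in the text are Yap1, Wwtr1, Pdgfra, Thbs1, Ccn1, Ccn2 and Ankrd1, then in each comparison the 8 with the largest change each way among those past the threshold, with at least 20 CPM in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes. For the interaction they are the 8 each way with the smallest p. Up to 4 members with the smallest p were taken from each list that passed camera, held at least 3 called genes or marks other cell types. Not every gene that the rule takes is named. A few further members are named to show the direction opposite to these, and were chosen after their values were seen.

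The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a non-robust fit, counts thinned to the smallest library, a block for the replicate number, a fit to only the groups compared, and each library left out in turn. Alternatives chosen after seeing the data were the share of satellite gene models or of Y-linked counts as a covariate, leaving out control overload replicate 2 and control sham replicate 3, protein-coding nuclear genes only, and the list tests with each library left out. Another scaling moved the median change of all genes by at most 0.04 on the log2 scale. The test was tried on simulated counts made from these libraries' means and sizes with 200 changed genes, 5 times per comparison. It found 70.4% to 78.0% of 4-fold and 18.0% to 23.6% of 2-fold changes for the comparisons of 2 groups, and 3.49% to 6.75% of its calls over all 5 comparisons were false.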

Results

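Fibro-adipogenic progenitors are Pdgfra-positive mesenchymal cells that lie between the fibres of skeletal muscle. They were sorted from plantaris muscles that had been overloaded or sham-operated. Control mice carried only the Pdgfra-CreERT2 driver, whereas conditional double knockout mice (cdKO) also carried floxed alleles of Yap1 and of Taz (gene symbol Wwtr1), 2 transcriptional co-activators of the Hippo pathway. The 4 groups (control sham, control overload, cdKO sham and cdKO overload) held 3 libraries each, made from 1000 sorted cells per tube. Of all genes, 8161 had enough counts to be tested. The design allows 5 comparisons: overload in each genotype, cdKO against control under each load, and the interaction. The interaction asks whether overload changed a gene differently in cdKO. The labels do not say that libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Libraries of the same group had a median correlation of 0.910, libraries of the same load but other genotype 0.911, and libraries of different load 0.816. Among overloaded libraries, control replicate 1 and cdKO replicate 2 lay nearest to sham on the first principal component, at 15.8 and 7.39 against 32.6 to 61.1 for the other 4.

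The targeted genes were read first in every library. Wwtr1 (chromosome 3, 57455649 to 57575910, minus strand, GRCm38) stood at 119 ± 9.95 counts-per-million (CPM, mean ± SD, n = 3) in control sham, 141 ± 28.4 in control overload, 34.8 ± 6.97 in cdKO sham and 20.2 ± 2.13 in cdKO overload. All 6 cdKO libraries lay below all 6 control libraries, from 18.2 to 40.6 against 108 to 174 CPM. Yap1 (chromosome 9, 7931999 to 8004596, minus strand) was at 97.9 ± 8.93 and 59.5 ± 27.9 CPM in control sham and overload, and at 64.5 ± 7.71 and 32.0 ± 9.15 CPM in the matching cdKO groups. In sham muscle the Yap1 values of the 2 genotypes did not overlap, but in overloaded muscle the highest cdKO library (40.2 CPM) exceeded the lowest control library (39.7 CPM). Wwtr1 fell in cdKO under both loads, by a log2 fold change of -2.78 ± 0.28 (SE) in overloaded muscle (edgeR adjusted p = 1.83e-06) and -1.74 ± 0.27 in sham muscle (adjusted p = 0.00733). Yap1 did not pass, at -0.85 ± 0.32 (adjusted p = 0.586) and -0.61 ± 0.30 (adjusted p = 0.999). The floxed exons are not given in the sources used here, and the library protocol counts 3′ ends, so reads outside a deleted exon do not check the deletion. Pdgfra (chromosome 5, 75152292 to 75198215), the receptor used for the sort, was counted in all 12 libraries and differed by -0.21 ± 0.25 between genotypes in overloaded muscle (adjusted p = 0.930).

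**Figure D1:**
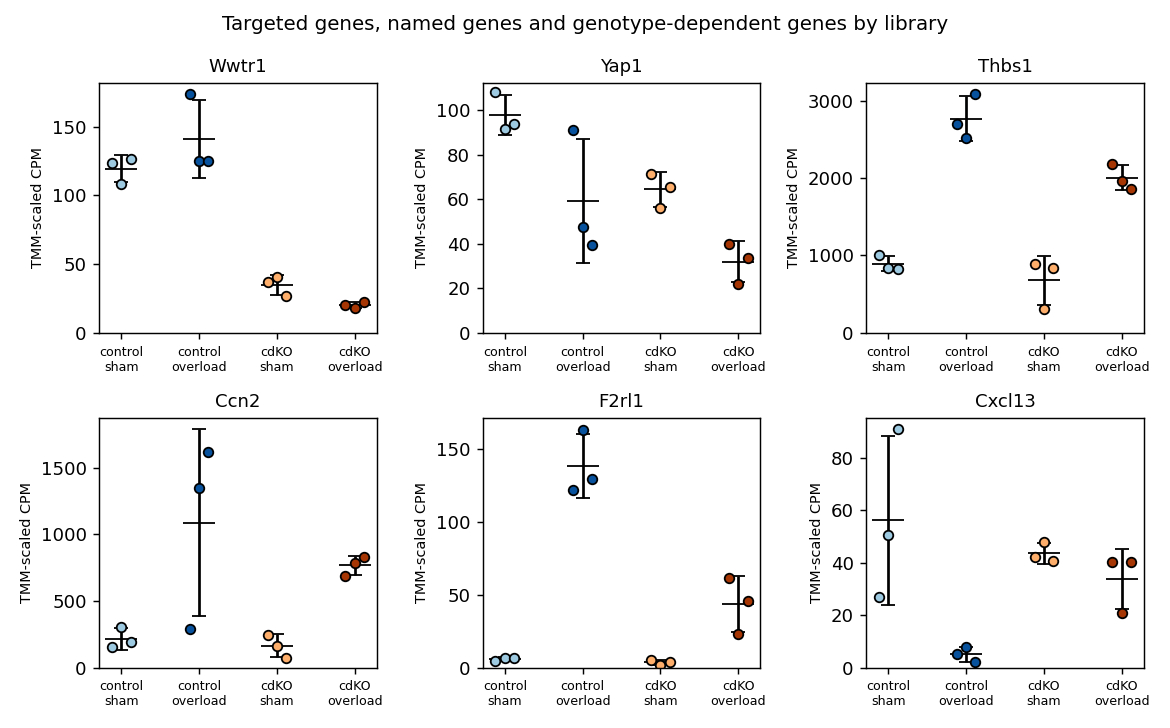
CPM of Wwtr1, Yap1, Thbs1, Ccn2, F2rl1 and Cxcl13 in each of the 12 libraries, 1 point per library, with bars at the mean and error bars of 1 SD over the 3 libraries of a group. Wwtr1 lay at 18.2 to 40.6 CPM in the cdKO libraries and at 108 to 174 CPM in the control libraries.

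Overload in control mice changed 1768 of the 8161 genes, with 867 higher and 901 lower (edgeR quasi-likelihood test, adjusted p under 0.05). The largest rises among abundant genes included those in Tnc, which encodes the matrix glycoprotein tenascin-C (log2 fold change 8.03 ± 0.58, adjusted p = 3.26e-08), Timp1, an inhibitor of matrix metalloproteinases (6.87 ± 0.58), and Il1rl1, the receptor of interleukin 33 (6.68 ± 0.59). Tnc went from 7.32 ± 6.64 to 1524 ± 447 CPM. Genes with no count in control sham are given as bounds against a floor of 3 counts per library: Ltbp2, a latent TGF-beta binding protein family member, was at least 3.67-fold higher, and Uhrf1, which maintains DNA methylation at replication, at least 3.43-fold. Cthrc1, a secreted collagen-associated protein, had a ratio of 234 (95% counting interval 41.8 to 9272), and Cdk1, the mitotic kinase, a ratio of 82.2 (27.98 to 400.2). The largest falls were in Inmt, a methyltransferase (-4.75 ± 1.13, adjusted p = 0.0180), Galnt15, a glycosyltransferase (-4.40 ± 1.20), Ccn3, a matricellular protein (-4.21 ± 0.36), Ntf3, a neurotrophin (-4.01 ± 0.81), Scara5, a ferritin receptor (-3.92 ± 0.38), Irgm1, an interferon-induced GTPase (-3.73 ± 0.40), and Slco2b1, an organic anion transporter (-3.68 ± 0.70). G0s2, an inhibitor of lipolysis, was lower by a ratio of 24.1 (7.61 to 122). Of the called genes, 678 rose and 757 fell at least 2-fold. Without control overload replicate 2 the count was 1060, without that library and control sham replicate 3 it was 712, and with the share of Y-linked counts as a covariate it was 623, with 3 called genes changing sign.

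Thbs1 (chromosome 2, 118111876 to 118127133), which encodes the secreted glycoprotein thrombospondin-1, rose from 893 ± 98.5 to 2767 ± 295 CPM (1.63 ± 0.30, adjusted p = 3.79e-04). Among 16 tested target genes of YAP, TAZ and their partner TEAD, 2 rose, 4 fell and 10 did not pass, or 3 and 4 adjusted over the list alone. Ccn2 (chromosome 10, 24595442 to 24598683), a connective tissue growth factor, rose (2.31 ± 0.57), as did the matrix protein gene Ccdc80 (1.12 ± 0.24), while F3, which encodes tissue factor (-1.88 ± 0.33), the growth arrest gene Gadd45a (-1.12 ± 0.25) and Crim1 (-1.28 ± 0.36) fell. Ccn1 (chromosome 3, 145646976 to 145649981) did not pass (-0.57 ± 0.35, adjusted p = 0.263), and Ankrd1 had 0 to 9 counts per library and was not tested. Of 16 Hippo pathway and TEAD genes, 2 rose, 1 fell and 13 did not pass (2 and 2 adjusted over the list alone), with Tead1 (1.01 ± 0.26) and its co-factor Vgll3 (1.16 ± 0.37) higher and Amotl1 (-1.01 ± 0.26) lower. Neither list stood apart from other genes by camera (adjusted p = 0.500 and 0.873).

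Matrix genes changed in both directions. For matrix assembly and crosslinking, 14 rose, 3 fell and 16 did not pass of 33 (16 and 5 adjusted over the list alone), led by Postn, encoding periostin (5.51 ± 0.41), and Lox, the lysyl oxidase that crosslinks collagen (4.09 ± 0.33), against falls in the proteoglycan decorin (Dcn, -2.32 ± 0.30) and Fbln5 (-2.32 ± 0.38). Of 15 genes in the list of fibrillar and type VI collagens, which also holds a few collagens of other classes, 5 rose, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone), including the fibrillar Col3a1 (1.53 ± 0.27) and, from other classes, Col8a1 (3.50 ± 0.32) and Col12a1 (1.87 ± 0.25). In the actin and myofibroblast list of 23, 14 rose, 0 fell and 9 did not pass (21 and 0 adjusted over the list alone), among them Acta2, the smooth muscle actin of myofibroblasts (4.54 ± 0.53), and Actn1, alpha-actinin (2.56 ± 0.30). Of 13 basement membrane genes, 0 rose, 5 fell and 8 did not pass (0 and 7 adjusted over the list alone), with Sparcl1 (-1.51 ± 0.29), Nid1, encoding nidogen (-1.31 ± 0.27), and Lama2, a laminin chain (-1.17 ± 0.32). camera placed these 4 lists apart from other genes, at adjusted p = 8.55e-08, 2.07e-04, 2.27e-10 and 0.00435. With an estimated correlation the adjusted p = 0.0877, 0.197, 0.153 and 0.503. For matrix-degrading enzymes and inhibitors, 2 rose, 6 fell and 8 did not pass of 16 (2 and 6 adjusted over the list alone, camera adjusted p = 0.546). Timp1 was among the higher genes and Timp2 (-1.88 ± 0.28) among the lower.

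Most genes typical of resting progenitors fell. In the progenitor identity and quiescence list, 1 rose, 19 fell and 3 did not pass of 23 (1 and 19 adjusted over the list alone). They included Gsn, encoding the actin-severing protein gelsolin, which went from 38538 ± 5851 to 6646 ± 2127 CPM (-2.54 ± 0.32), Dpep1, a dipeptidase (-2.53 ± 0.27), Efemp1, a fibulin (-2.33 ± 0.26), and Hsd11b1, which regenerates glucocorticoid (-1.83 ± 0.24), while the chemokine gene Cxcl14 rose (1.80 ± 0.25). Of 12 adipogenic genes, 0 rose, 4 fell and 8 did not pass (0 and 5 adjusted over the list alone), with Cebpd, an early adipogenic transcription factor (-1.84 ± 0.30), and Lpl, lipoprotein lipase (-1.55 ± 0.29), lower. In the tenogenic list 3 rose, 1 fell and 4 did not pass of 8 (3 and 1 adjusted over the list alone), with Thbs4 (4.45 ± 0.42) and Prg4, encoding lubricin (3.10 ± 0.30), higher and Egr1 (-1.81 ± 0.43) lower. In the chondrogenic and osteogenic list 4 rose, 3 fell and 5 did not pass of 12 (5 and 3 adjusted over the list alone), with Cilp, a cartilage matrix protein (3.14 ± 0.27), and the transcription factor Runx1 (1.99 ± 0.27) higher and Bmp2 (-2.06 ± 0.26) lower. The adjusted p by camera was 1.51e-15, 0.00227, 0.00521 and 0.0673 for the 4 lists in this order. These became adjusted p = 0.173, 0.310, 0.153 and 0.232 with an estimated correlation. The camera direction of the tenogenic and chondrogenic lists was up and their means were 0.76 and 0.62, but their medians were -0.27 and -0.08. Without control overload replicate 1 the tenogenic list was at adjusted p = 0.0826. For the matrix-degrading list the median was -0.12 and the mean 0.13.

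Most cell cycle genes and most genes of folding in the endoplasmic reticulum rose. Of 18 S phase genes, 13 rose, 0 fell and 5 did not pass (15 and 0 adjusted over the list alone). Of 14 G2 and M phase genes, 10 rose, 0 fell and 4 did not pass (13 and 0 adjusted over the list alone). Examples were Rrm2, a ribonucleotide reductase subunit (3.54 ± 0.57), Lig1, a DNA ligase (2.63 ± 0.47), Top2a, a topoisomerase (4.08 ± 0.48), and Tpx2, a spindle protein (3.86 ± 0.54). In the list for the unfolded protein response and folding in the endoplasmic reticulum, 16 rose, 0 fell and 5 did not pass of 21 (16 and 1 adjusted over the list alone), such as Pdia6, a disulfide isomerase (1.98 ± 0.30), Calr, calreticulin (1.62 ± 0.26), and Sec61b, a translocon subunit (2.15 ± 0.30). For ribosome biogenesis and MYC targets 12 rose, 1 fell and 9 did not pass of 22 (13 and 1 adjusted over the list alone), among them Srm, spermidine synthase (2.10 ± 0.31), and Ncl, nucleolin (1.18 ± 0.25). These 4 lists had adjusted p = 2.31e-07, 5.32e-08, 7.95e-09 and 2.15e-05 by camera, all upward. They were adjusted p = 0.260, 0.197, 0.247 and 0.197 with an estimated correlation. Of 18 glycolysis and hypoxia genes, 7 rose, 1 fell and 10 did not pass (10 and 2 adjusted over the list alone), with Pgam1, phosphoglycerate mutase (1.77 ± 0.29), and Pkm, pyruvate kinase (2.13 ± 0.39), higher. Of 33 nuclear genes of the respiratory chain, 7 rose, 0 fell and 26 did not pass (7 and 0 adjusted over the list alone), led by Uqcrq (2.22 ± 0.32). Of 41 cytosolic ribosomal protein genes, whose reads can be shared with pseudogenes, 3 rose, 0 fell and 38 did not pass (2 and 0 adjusted over the list alone), including Rps2 (1.37 ± 0.31). camera gave adjusted p = 0.00775, 8.10e-05 and 0.00298 for these 3 lists, and adjusted p = 0.458, 0.487 and 0.658 with an estimated correlation. The Y-linked covariate put the respiratory chain at adjusted p = 0.0576 and ribosomal proteins at 0.980, and the satellite covariate put ribosomal proteins at 0.160. Of 15 genes of the mitochondrial genome, 3 rose, 0 fell and 12 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.0764), among them mt-Nd5, a complex I subunit (1.01 ± 0.26).

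Of 22 interferon response genes, 0 rose, 16 fell and 6 did not pass (0 and 19 adjusted over the list alone), including the GTPase genes Gbp2 (-2.93 ± 0.30) and Iigp1 (-3.20 ± 0.35) and the signal transducer Stat2 (-2.73 ± 0.38). For class I antigen presentation 0 rose, 6 fell and 2 did not pass of 8 (0 and 7 adjusted over the list alone), such as B2m, beta-2 microglobulin (-1.75 ± 0.30), and Tap2, a peptide transporter (-2.22 ± 0.45). Reads of H2-D1 (-1.52 ± 0.27) can be shared with near-identical family members. Of 10 complement genes, 0 rose, 8 fell and 2 did not pass (0 and 9 adjusted over the list alone), among them Serping1, the C1 inhibitor (-1.78 ± 0.29). In the list of immediate early genes, which also mark tissue dissociation, 3 rose, 16 fell and 7 did not pass of 26 (3 and 18 adjusted over the list alone). Examples were the phosphatase gene Dusp1 (-1.94 ± 0.26) and Junb (-1.90 ± 0.31), both lower, and Ier3 (1.76 ± 0.34), higher. The adjusted p by camera was 3.86e-14, 1.24e-04, 6.13e-07 and 2.26e-06, all downward, and adjusted p = 0.153, 0.173, 0.197 and 0.260 with an estimated correlation. Of 25 cytokine and chemokine genes, 10 rose, 4 fell and 11 did not pass (11 and 6 adjusted over the list alone), with Ccl2, a monocyte chemoattractant (3.30 ± 0.34), and Cxcl5, a neutrophil chemoattractant (4.71 ± 0.42), higher and Cxcl13, a B cell chemoattractant (-3.25 ± 0.47), lower. Of 21 genes for secreted signals to muscle stem cells, 7 rose, 4 fell and 10 did not pass (7 and 4 adjusted over the list alone), with Inhba, an activin subunit (4.18 ± 0.48), Il11 (4.30 ± 0.54) and Ccn4 (3.88 ± 0.40) higher and Bmp4 (-1.53 ± 0.39) lower. For these 2 lists camera gave adjusted p = 0.00270 and 0.00780, upward, and adjusted p = 0.471 and 0.232 with an estimated correlation.

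Markers of other cell types that the sort could hold were counted beside these groups. Of 8 endothelial genes, 0 rose, 1 fell and 7 did not pass (0 and 1 adjusted over the list alone), the faller being the angiopoietin receptor Tek (-2.13 ± 0.38). Of 8 pericyte and smooth muscle genes, 0 rose, 2 fell and 6 did not pass (0 and 2 adjusted over the list alone), Vtn (-2.30 ± 0.37) and Steap4 (-0.98 ± 0.25). camera gave adjusted p = 0.0299 and 0.0263, downward, and adjusted p = 0.552 and 0.258 with an estimated correlation. The endothelial list was at adjusted p = 0.126 without control sham replicate 1 and 0.128 without control overload replicate 2. With the Y-linked covariate the endothelial list was at adjusted p = 0.410 and the adipogenic and pericyte lists at 0.189, and with the satellite covariate the endothelial list was at 0.248. Of 3 Schwann and nerve genes, 0 rose, 1 fell and 2 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.148), the faller being the myelin gene Pmp22 (-1.05 ± 0.26). In the muscle stem cell and myoblast list 1 rose, 1 fell and 1 did not pass of 3 (1 and 1 adjusted over the list alone), Msc (1.61 ± 0.49) and Des, desmin (-1.35 ± 0.48), with camera adjusted p = 0.995. Pax7, Myf5, Myod1 and Myog of this list had too few counts to be tested. Among myofibre markers only Tnnt3 (-2.19 ± 0.91) and Ttn (-1.13 ± 0.68) were testable and neither passed over all genes, though Tnnt3 did when adjusted over the list alone. In the macrophage and myeloid list only Ptprc, a gene of all leukocytes, was testable, and it did not pass (-0.91 ± 1.256, adjusted p = 0.648), and 0 lymphocyte markers had enough counts. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs made up the testable erythroid list, and 0 of 3 passed (camera adjusted p = 0.188), with a list median of 6.05 as fitted and 2.84 with the floor bound for Hba-a1. The 5 sex-linked genes did not pass (camera adjusted p = 0.237), but summed Y-linked CPM was 63.9 and 67.9 in control overload replicates 2 and 3 against 111 to 253 in the other 10 libraries. These 2 libraries are overloaded controls, so the difference stands beside each gene group above. Gene models that overlap satellite repeats took 0.633% of counts in control overload replicate 2 and 3.91% to 11.3% elsewhere.

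Overload in cdKO mice changed 1065 genes, 520 higher and 545 lower. The largest rises included those in Timp1 (6.61 ± 0.57, adjusted p = 2.53e-06), Tnc (6.05 ± 0.49), Cthrc1 (5.85 ± 0.63), Postn (5.61 ± 0.41), Il1rl1 (4.69 ± 0.53) and Lox (3.90 ± 0.33). Spp1, osteopontin, had a ratio of 97.3 (95% counting interval 26.6 to 809). The largest falls were in Inmt (-4.33 ± 1.12), Fam124a (-3.88 ± 0.66), Fzd7, a Wnt receptor (-3.49 ± 0.72), Aqp1, a water channel (-3.43 ± 0.92), Enpp5 (-3.38 ± 0.57), Ppl, periplakin (-3.19 ± 0.59), and Selenbp1 (-2.99 ± 0.51), with Hba-a2 at least 5.87-fold lower than the cdKO sham mean. Thbs1 rose from 678 ± 316 to 2003 ± 163 CPM (1.57 ± 0.30, adjusted p = 0.00116), Ccn2 also rose (2.22 ± 0.57, adjusted p = 0.0251), and Pdgfra fell (-1.09 ± 0.26, adjusted p = 0.00620), as did Yap1 (-1.004 ± 0.32, adjusted p = 0.0379). In control Pdgfra was at -0.48 ± 0.26 (adjusted p = 0.186) and Yap1 at -0.76 ± 0.30 (adjusted p = 0.0699), and neither interaction passed (adjusted p = 0.940 and 0.978). With the Y-linked covariate Yap1 was at -0.15 in control (adjusted p = 0.875), whereas it passed with limma voom (-1.03) and the replicate block (-0.79). In cdKO Yap1 lost its call without any 1 of the 6 libraries compared (adjusted p = 0.0516 to 0.140) or without control sham replicate 2 (adjusted p = 0.0547), and with 1 library left out it passed in control only without control overload replicate 1 (-1.10, adjusted p = 0.00685, against 0.0656 to 0.295 without another). Of the called genes, 370 rose and 452 fell at least 2-fold. The count was 423 without cdKO overload replicate 3, 473 without cdKO overload replicate 1, 551 without cdKO sham replicate 2 and 702 with no filter on low counts.

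Of 16 YAP and TAZ target genes, 2 rose, 2 fell and 12 did not pass (2 and 3 adjusted over the list alone), with Ccn2 and Ccdc80 (0.99 ± 0.24) higher and F3 (-1.32 ± 0.31) and Amotl2, a YAP inhibitor (-1.40 ± 0.39), lower. Among Hippo pathway genes 0 rose, 2 fell and 14 did not pass of 16 (1 and 2 adjusted over the list alone). Neither list stood apart by camera (adjusted p = 0.424 and 0.348). Of 33 matrix assembly genes, 14 rose, 2 fell and 17 did not pass (14 and 2 adjusted over the list alone). Of 15 collagen genes, 5 rose, 0 fell and 10 did not pass (7 and 0), such as Col8a1 (2.60 ± 0.29). Of 13 basement membrane genes, 0 rose, 5 fell and 8 did not pass (0 and 6). In the actin and myofibroblast list 8 rose, 0 fell and 15 did not pass of 23 (16 and 0 adjusted over the list alone), with Acta2 (3.66 ± 0.51) and Tagln, transgelin (3.67 ± 0.64). These 4 lists had camera adjusted p = 5.12e-09, 1.24e-04, 0.00131 and 9.85e-09, and adjusted p = 0.0770, 0.197, 0.468 and 0.153 with an estimated correlation. Of 23 progenitor identity genes, 1 rose, 17 fell and 5 did not pass (1 and 18 adjusted over the list alone), with Dpep1 (-2.30 ± 0.27) and Smoc2 (-1.59 ± 0.25) lower. The adipogenic list had 0 risen, 2 fallen and 10 not passed of 12 (0 and 3 adjusted over the list alone), the tenogenic list 3, 1 and 4 of 8 (3 and 1), and the chondrogenic list 5, 2 and 5 of 12 (5 and 3). Examples were Lpl (-1.55 ± 0.28), Thbs4 (3.59 ± 0.40) and Cilp (2.39 ± 0.26). For the identity, adipogenic, tenogenic and chondrogenic lists camera gave adjusted p = 1.42e-16, 0.0299, 0.00291 and 0.00534, and adjusted p = 0.153, 0.503, 0.153 and 0.153 with an estimated correlation. Without cdKO sham replicate 1 the adipogenic list was at adjusted p = 0.0710. Of 16 matrix-degrading genes, 2 rose, 3 fell and 11 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.353), among them Timp3 (-1.69 ± 0.27).

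Of 18 S phase genes, 4 rose, 0 fell and 14 did not pass in cdKO (9 and 0 adjusted over the list alone). Of 14 G2 and M phase genes, 2 rose, 0 fell and 12 did not pass (5 and 0), with Mcm4, a replication helicase subunit (1.54 ± 0.40), and Top2a (1.99 ± 0.45) higher. In the unfolded protein list 12 rose, 0 fell and 9 did not pass of 21 (13 and 0 adjusted over the list alone). For ribosome biogenesis 6 rose, 1 fell and 15 did not pass of 22 (8 and 1). For the nuclear respiratory chain 5 rose, 0 fell and 28 did not pass of 33 (11 and 0), and for ribosomal proteins 6 rose, 0 fell and 35 did not pass of 41 (11 and 0). Hyou1, a chaperone (1.86 ± 0.33), Srm (1.58 ± 0.30) and Uqcrq (1.47 ± 0.29) were examples. The 6 lists had camera adjusted p = 8.69e-04, 0.00227, 2.26e-08, 8.60e-05, 2.38e-05 and 4.46e-07, all upward. With an estimated correlation these were adjusted p = 0.486, 0.458, 0.258, 0.232, 0.462 and 0.487. Of 22 interferon genes, 0 rose, 14 fell and 8 did not pass (0 and 17 adjusted over the list alone). Of 8 class I presentation genes, 0 rose, 2 fell and 6 did not pass (0 and 5). Of 10 complement genes, 0 rose, 4 fell and 6 did not pass (0 and 8), and of 26 immediate early genes, 2 rose, 10 fell and 14 did not pass (2 and 14). Examples were Gbp2 (-1.70 ± 0.29), Psmb8, an immunoproteasome subunit (-1.35 ± 0.40), Cd55, a complement regulator (-1.35 ± 0.31), and Fos (-2.08 ± 0.36). camera gave adjusted p = 1.50e-12, 0.00313, 0.00115 and 1.18e-05, downward, and adjusted p = 0.153, 0.197, 0.310 and 0.268 with an estimated correlation. Of 25 cytokine genes, 12 rose, 2 fell and 11 did not pass (14 and 3 adjusted over the list alone), with Ccl2 (2.997 ± 0.34) and Lcn2, lipocalin 2 (3.60 ± 0.55), higher. Of 21 genes of secreted signals, 8 rose, 3 fell and 10 did not pass (8 and 4), with Inhba (3.82 ± 0.46) and Il33 (1.48 ± 0.27) higher. Their camera adjusted p was 3.51e-08 and 0.00288, and adjusted p = 0.208 and 0.197 with an estimated correlation. Of 8 endothelial genes, 0 rose, 2 fell and 6 did not pass (0 and 5 adjusted over the list alone), Tek (-1.30 ± 0.37) and Tie1 (ratio 17.7, counting interval 4.50 to 152). Of 8 pericyte genes, 0 rose, 2 fell and 6 did not pass (0 and 3), and of 3 erythroid genes, 0 rose, 1 fell and 2 did not pass (0 and 3). The 3 lists had camera adjusted p = 0.00188, 0.0267 and 0.0479, downward, and adjusted p = 0.462, 0.258 and 0.487 with an estimated correlation. The erythroid list was at adjusted p = 0.0856, 0.0579 and 0.0696 without cdKO sham replicate 2, cdKO sham replicate 3 or cdKO overload replicate 2. Of 3 Schwann genes, 0 rose, 2 fell and 1 did not pass (camera adjusted p = 0.0789). The mitochondrial genome list (0 rose, 2 fell and 13 did not pass of 15, camera adjusted p = 0.916, downward) had a median of 0.06 and a mean of -0.10. Of 18 glycolysis genes, 4 rose, 1 fell and 13 did not pass (camera adjusted p = 0.102).

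The genes called for overload overlapped between the genotypes beyond what independent lists would share. Of the genes called in control, 380 of those that rose also rose in cdKO and 408 of those that fell also fell, where 55.2 and 60.2 would be shared by independent lists, and 0 were called in opposite directions. Of the genes raised in control 97.1% had the same direction in cdKO, and of those lowered 96.2%. These 2 comparisons share no library, and their log2 fold changes correlated across genes at 0.714, against -0.00778 simulated with no effect, with a covariance of 0.610 against a simulated -0.00152. Genes are not independent replicates. Genes chosen in control had smaller median changes in cdKO (ratio 0.664 for raised genes and 0.639 for lowered genes), whereas genes chosen in cdKO had ratios of 0.979 and 1.07 (control over cdKO). Among 1346 genes raised and 1384 lowered by the mean of both effects, the median changes were 1.05 and -1.24 in control and 0.85 and -0.99 in cdKO.

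**Figure D2:**
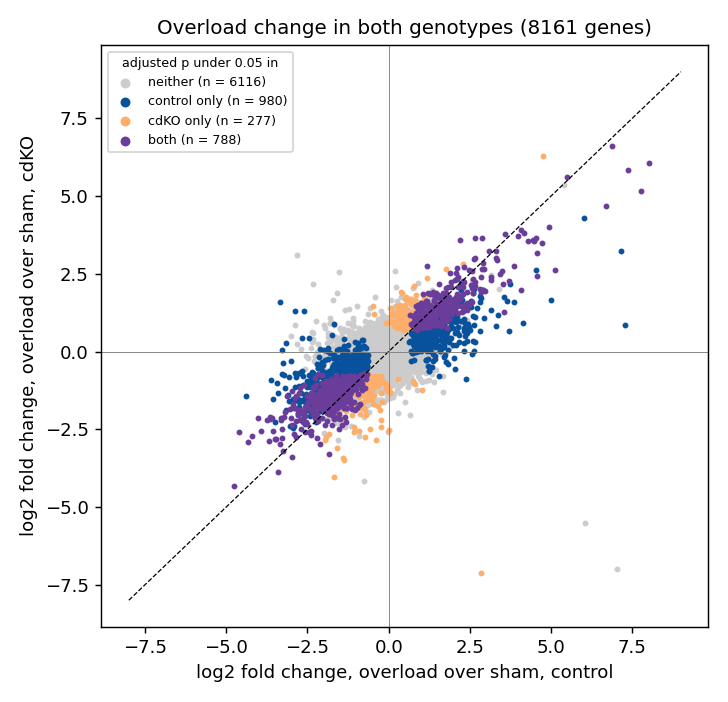
Log2 fold change by overload in control (x axis) against that in cdKO (y axis) for the 8161 tested genes, 1 point per gene, coloured by where the gene was called. Of these genes 788 were called in both genotypes, 980 in control alone, 277 in cdKO alone and 6116 in neither, and a call in 1 genotype alone is no test of a difference.

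In overloaded muscle, cdKO differed from control in 3 genes (edgeR, 569 genes with an unadjusted p under 0.05, where 408 are expected). Apart from Wwtr1, F2rl1 (chromosome 13, 95511732 to 95525227), which encodes protease-activated receptor 2, fell from 138 ± 22.0 to 43.7 ± 19.3 CPM (-1.68 ± 0.29, adjusted p = 0.0221), and Cxcl13 (chromosome 5, 95956951 to 95961068) was higher, at 33.8 ± 11.3 against 5.10 ± 2.73 CPM (2.58 ± 0.47, adjusted p = 0.0250). All 3 libraries of each group were on the same side for both genes. Thbs1 (-0.47 ± 0.29, adjusted p = 0.815) and Ccn2 (-0.50 ± 0.53, adjusted p = 0.920) did not pass. DESeq2 called Wwtr1 alone (513 genes at an unadjusted p under 0.05), and limma voom called Wwtr1 and F2rl1 (890). With no filter on low counts edgeR called 17, of which 4 were higher and 13 lower. Without control overload replicate 1, edgeR called 34 genes. F2rl1 lost its call without control overload replicate 2 or 3 or cdKO overload replicate 2 or 3 (adjusted p = 0.193, 0.0733, 0.154 and 0.131). Cxcl13 lost it without control overload replicate 3, cdKO overload replicate 1 or 3, control sham replicate 2 or cdKO sham replicate 1 (adjusted p = 0.350, 0.266, 0.149, 0.0534 and 0.0529). With the Y-linked covariate both lost it, at -1.77 ± 0.44 for F2rl1 (adjusted p = 0.348) and 2.21 ± 0.69 for Cxcl13 (adjusted p = 0.751). They also did with thinned counts, at -1.17 ± 0.33 and 2.88 ± 0.65 (adjusted p = 0.483 and 0.190), and in a fit to only the 2 groups compared, at -1.68 ± 0.30 and 2.59 ± 0.47 (adjusted p = 0.0763 each). In simulated data 78.0% of 4-fold and 23.6% of 2-fold changes were found in this comparison.

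Cell cycle genes were lower as a set in overloaded cdKO than in overloaded control cells, though no member passed over all genes. Adjusted over the list alone, 13 of 18 S phase and 8 of 14 G2 and M phase genes were lower. Examples were Tpx2 (-1.89 ± 0.39), Top2a (-1.46 ± 0.35), Mki67 (-2.01 ± 0.56), Lig1 (-1.53 ± 0.38) and Rrm2 (-1.69 ± 0.45). camera gave adjusted p = 8.53e-14 and 1.08e-15, and adjusted p = 0.185 and 0.153 with an estimated correlation. Mean log2 CPM of the 32 members was 4.73, 5.71 and 5.46 in the control overload libraries and 4.58, 3.76 and 4.42 in the cdKO overload libraries, where the Y-linked counts and satellite shares given above also differed. The lowest mean was in cdKO overload replicate 2, also the overloaded library nearest to sham. Other lists that lay lower were ribosome biogenesis, actin and myofibroblast, sterol biosynthesis, glycolysis and hypoxia, Hippo pathway genes, the unfolded protein list and the erythroid list, with camera adjusted p = 7.69e-06, 1.10e-04, 0.00135, 0.00912, 0.0226, 0.0250 and 1.85e-04. With an estimated correlation these were adjusted p = 0.197, 0.232, 0.247, 0.458, 0.263, 0.625 and 0.197. In these 7 lists 0 members passed over all genes. Adjusted over the list alone, only the Hippo genes Amotl2 (-1.59 ± 0.37) and Vgll3 (-1.18 ± 0.35), the glycolytic gene Gapdh (-1.34 ± 0.40), whose reads can be shared with pseudogenes, and the 3 haemoglobin genes passed. Lists that lay higher were complement, chondrogenic and osteogenic, sex-linked, basement membrane and collagen genes, at camera adjusted p = 1.25e-05, 0.00188, 0.00527, 0.00667 and 0.0354, and adjusted p = 0.197, 0.153, 0.187, 0.528 and 0.455 with an estimated correlation. Their members passing over the list alone included C3 (0.74 ± 0.25), Bmp2 (0.98 ± 0.25) and Mgp (0.96 ± 0.28). The Y-linked genes Uty (1.54 ± 0.51), Eif2s3y (1.17 ± 0.39) and Ddx3y (1.20 ± 0.47) also passed. Xist, also sex-linked, lay lower, at 2.89, 90.5 and 3.15 CPM in cdKO against 97.2 to 99.96 in control. Without 1 overloaded library the highest adjusted p was 0.233 for Hippo (cdKO replicate 3), 0.610 and 0.964 for basement membrane and unfolded protein (cdKO replicate 2), 0.479 for collagens (control replicate 3) and 0.480 for glycolysis (control replicate 2). With the Y-linked covariate 7 of these lists lost their call, at adjusted p = 0.0570 (basement membrane) to 0.741 (sex-linked genes). The other 20 lists tested did not pass, among them YAP and TAZ targets (adjusted p = 0.927) and matrix assembly (0.191). For the YAP and TAZ, interferon and heat shock lists the median (0.15, -0.10 and 0.05), mean (-0.05, 0.03 and 0.01) and camera direction (down, up and down) differed in sign.

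**Figure D3:**
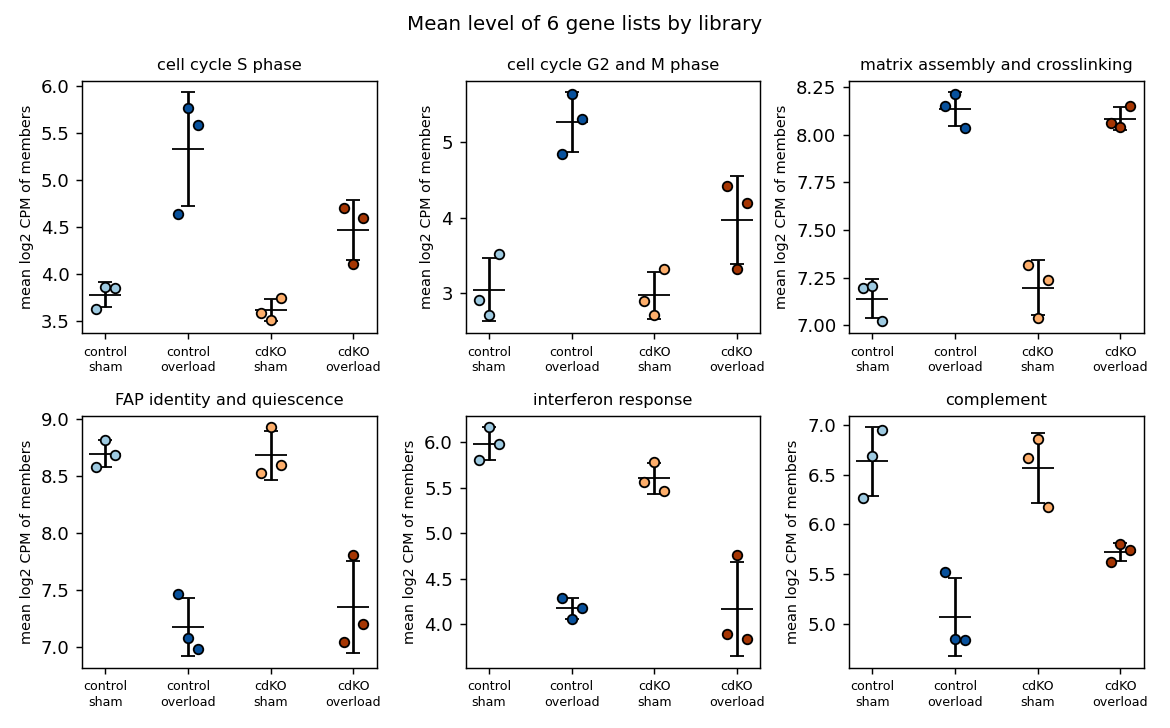
Mean log2 CPM of the tested members of 6 gene lists in each of the 12 libraries, 1 point per library, with bars at the group mean and error bars of 1 SD (n = 3). G2 and M phase genes were at 5.27 ± 0.40 in control overload and 3.98 ± 0.58 in cdKO overload, and at 3.05 ± 0.42 and 2.98 ± 0.31 in the sham groups.

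In sham muscle edgeR called Wwtr1 alone between genotypes over all 12 libraries (334 genes with an unadjusted p under 0.05). Cilp, chosen after its values were seen, was at 389 ± 17.7 CPM in cdKO and 156 ± 35.1 in control (1.33 ± 0.26, adjusted p = 0.115), and it passed with DESeq2 and limma voom, which each called Cilp and Wwtr1 (251 and 384 genes at an unadjusted p under 0.05), as did edgeR fitted to only the 2 sham groups (308). Collagen genes lay higher in cdKO, with Col8a1 (1.14 ± 0.33) passing over the list alone, as did the basement membrane, tenogenic and chondrogenic lists, at camera adjusted p = 9.91e-05, 0.0133, 0.0347 and 0.0109, and adjusted p = 0.197, 0.552, 0.197 and 0.173 with an estimated correlation. Mitochondrial genome genes also lay higher, with mt-Nd4l (1.16 ± 0.34) passing over the list alone, and ribosomal protein genes lay lower. Beside these lists, the mitochondrial share of counts was 12.5% ± 1.32 in cdKO sham and 8.65% ± 1.42 in control sham, with no overlap (11.6% to 13.98% against 7.39% to 10.2%, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Interferon, matrix-degrading and ribosome biogenesis genes lay lower and the erythroid list higher. camera gave adjusted p = 8.32e-05, 1.09e-05, 6.26e-05, 0.0241, 0.0325 and 8.68e-04 for these 6 lists in the order named, and adjusted p = 0.232, 0.528, 0.264, 0.221, 0.487 and 0.232 with an estimated correlation. In these 10 lists 0 genes passed over all genes. Without 1 library the highest adjusted p was 0.189 for ribosomal proteins, 0.266 for tenogenic (both control sham replicate 2), 0.274 for matrix-degrading, 0.382 for ribosome biogenesis, 0.141 for basement membrane (all cdKO sham replicate 2) and 0.0593 for chondrogenic (control sham replicate 3). The cell cycle lists did not pass (camera adjusted p = 0.254 and 0.732). Signs of median, mean and test differed for the YAP and TAZ, matrix assembly, identity, complement, TGF-beta and Schwann lists, none of which passed. Wwtr1 lost its call without control sham replicate 1 or 3 or cdKO sham replicate 1 or 3, when the smallest adjusted p was 0.0672, 0.0625, 0.0683 and 0.135.

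The interaction called 0 genes by edgeR (427 with an unadjusted p under 0.05, where 408 are expected) and 0 by limma voom (647), while DESeq2 called 1, Procr (446). Procr (chromosome 2, 155751117 to 155755471), which encodes the endothelial protein C receptor, had the smallest p. It fell with overload in control (-1.69 ± 0.34, adjusted p = 0.00113) and stood at 0.87 ± 0.33 in cdKO (adjusted p = 0.0853), an interaction of 2.56 ± 0.47 (adjusted p = 0.167). Next by p among genes with a higher change in cdKO were Cxcl13 (2.87 ± 0.60, adjusted p = 0.183), the sorting nexin gene Snx10 (1.78 ± 0.39), Pcolce2, a procollagen proteinase enhancer (1.43 ± 0.34), Angptl7 (1.69 ± 0.40), Parp14 (2.56 ± 0.62), Qpct (2.72 ± 0.66) and Ifi205 (1.63 ± 0.42). On the other side were Aph1a, a gamma-secretase subunit (-3.28 ± 0.67), Smarce1 (-1.84 ± 0.44), the homeobox gene Meox1 (-1.71 ± 0.43), Rasl11a (-2.55 ± 0.65), the kinase genes Pak1 (-2.27 ± 0.59) and Map2k7 (-1.88 ± 0.53), Rfc1 (-1.83 ± 0.52) and Haus6 (-2.61 ± 0.75), and none of these 16 passed in this fit. With no filter on low counts edgeR called 10 genes, Procr (2.52 ± 0.42, adjusted p = 2.64e-05) and Cxcl13 (adjusted p = 0.0172) among them. Procr also passed with thinned counts (adjusted p = 0.0399), without control sham replicate 1 (adjusted p = 0.00723) and without cdKO overload replicate 2 (adjusted p = 0.00569). Thbs1 (-0.06 ± 0.42), Ccn2 (-0.08 ± 0.78) and Yap1 (-0.24 ± 0.44) did not pass either. Of 34 lists 12 passed by camera with 0 genes called in any. They were led by the erythroid list, lower in cdKO (adjusted p = 2.52e-07), G2 and M phase genes, lower (adjusted p = 5.45e-05), and complement genes, higher (adjusted p = 1.70e-04). These were adjusted p = 0.153, 0.260 and 0.247 with an estimated correlation. Complement genes fell by overload in both genotypes (median -1.85 in control and -0.97 in cdKO), so higher here means a smaller fall. The complement list was at adjusted p = 0.122 with the Y-linked covariate, and of the 12 lists only the erythroid and G2 and M phase lists passed in all 15 settings with libraries left out or a covariate. YAP and TAZ targets did not pass (adjusted p = 0.981), and the median, mean and test of that list, of heat shock and of the Schwann list differed in sign. In simulated data 46.4% of 4-fold and 4.80% of 2-fold interactions were found.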

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

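The haemoglobin test, the comparison of cell cycle genes with genes raised on average in both genotypes, and the use of the spread between libraries for the cell cycle lists were chosen after the result was seen, as were the tests with the satellite and Y-linked covariates and with libraries left out of the list tests.

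In 12 lists the effect of overload differed between the genotypes by camera on the interaction, although edgeR called 0 single genes (427 at an unadjusted p under 0.05) and DESeq2 called 1. Complement genes had a higher change in cdKO (adjusted p = 1.70e-04, but adjusted p = 0.247 with an estimated correlation), with a median interaction of 0.73 and Serping1 at 0.91 ± 0.40. As above, the higher change is a smaller fall. Interferon response genes likewise lay higher (median 0.39, adjusted p = 0.0177, but adjusted p = 0.528 with an estimated correlation), with Gbp2 at 1.23 ± 0.41, as did class I presentation genes (median 0.53, adjusted p = 0.0299, but adjusted p = 0.323 with an estimated correlation), with B2m at 1.17 ± 0.41. Both lists also fell less, with overload medians of -2.03 in control and -1.76 in cdKO for interferon, and -1.36 and -1.04 for class I. The interferon call held in 10 of 15 settings with libraries left out or a covariate. It was at adjusted p = 0.785 without cdKO overload replicate 2, nearest to sham. The class I call held in 8 of 15 and was at adjusted p = 0.702 with the Y-linked covariate. Matrix-degrading genes lay higher (median 0.35, adjusted p = 0.0152, but 0.197 with an estimated correlation). So did cytokines and chemokines (median 0.34, adjusted p = 0.0446, but 0.593 with an estimated correlation). Il6 was at 1.16 ± 0.46 and Il1rl1 at -1.99 ± 0.89. The cytokine call held in 7 of 15 settings and was at adjusted p = 0.943 with the Y-linked covariate. Mitochondrial genome genes lay lower (median -0.46, adjusted p = 0.00173, but adjusted p = 0.310 with an estimated correlation), beside the higher mitochondrial share of counts in cdKO sham. Actin and myofibroblast genes lay lower (median -0.24, adjusted p = 0.0135, but adjusted p = 0.458 with an estimated correlation), with Actn1 at -0.97 ± 0.41, and so did glycolysis and hypoxia genes (median -0.38, adjusted p = 0.0479, but adjusted p = 0.528 with an estimated correlation). Sex-linked genes lay higher (median 1.27, adjusted p = 0.00527, but 0.187 with an estimated correlation), with Uty at 2.57 ± 0.76. Y-linked CPM was lowest in control overload replicates 2 and 3, and Xist in cdKO overload replicates 1 and 3.

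S phase genes (adjusted p = 0.00198, but adjusted p = 0.487 with an estimated correlation, 0.0612 without control overload replicate 2, 0.0522 without cdKO overload replicate 2 and 0.582 with the Y-linked covariate) and G2 and M phase genes (adjusted p = 5.45e-05, but adjusted p = 0.260 with an estimated correlation) had a lower change by overload in cdKO, and in overloaded muscle their 32 members had a median log2 fold change of -1.14 between genotypes (mean difference between libraries -1.05 ± 0.30, and median -0.91 and mean -0.80 ± 0.29 without cdKO overload replicate 2, the overloaded library nearest to sham). A smaller response of all overload genes in cdKO remains possible. The members' median interaction of -0.91 lay at percentile 0 of 10000 random gene lists of like mean response (random median -0.34, 5th percentile -0.53). Between libraries the difference from such genes was -0.58 ± 0.25, in the main setting only. Random lists ignore correlation between members. Genes chosen in control gave percentile 47.5, but that choice enlarges their control change. Neither percentile decides. For the difference in overloaded muscle, the median was -0.93 and the mean difference between libraries -0.84 ± 0.31 without control overload replicate 2. With the satellite covariate they were -1.01 and -0.91 ± 0.29. Control overload replicate 2 also had the lowest satellite share, so these 2 tests overlap. They argue only weakly against that library alone, or genomic background, as the whole cause. Each mean difference stayed below the bound of -0.5 by little more than 1 SE. An unequal share of male and female cells cannot be told apart from an effect of genotype, since with the Y-linked covariate the median was -0.81 but the mean difference between libraries, -0.86 ± 0.43, lay below that bound by less than 1 SE.

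Haemoglobin genes (Hba-a1, Hba-a2 and Hbb-bs) had a lower change by overload in cdKO (adjusted p = 2.52e-07, but adjusted p = 0.153 with an estimated correlation). Their counts moved together across libraries: all 3 genes were above 3 counts, or all at or under 3, in 10 of the 12 libraries. Most of these 10 agreed because every gene had at most 2 counts, so the agreement says little by itself. They had 28 to 80 counts each in control overload replicate 1, 23 to 36 in cdKO sham replicate 2 and 17 to 22 in cdKO sham replicate 3, but at most 2 in the control sham libraries. This is consistent with red cell RNA carried into some libraries, which the sort for Pdgfra should remove, and no biological explanation was tested.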

How the results depend on the processing

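Chosen after the data were seen were the satellite and Y-linked covariates, the fit without the 2 doubted libraries (control overload replicate 2 and control sham replicate 3), the fit to protein-coding nuclear genes, and the list tests with each library left out.

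Of 12232 values for named genes under the alternatives, 11655 kept their side of the threshold, 469 lost it, 108 gained it and 0 changed direction past it. The DESeq2 and upper-quartile factors, the non-robust fit, the replicate block and the protein-coding fit moved no count of calls by over 1.5 times. With no filter, which tests 37990 genes, overload lowered 577 genes in control and 347 in cdKO. There cdKO in overloaded muscle had 4 higher and 13 lower, and the interaction 3 and 7. DESeq2 called 0 higher and 1 lower for cdKO in overloaded muscle, 1 higher (Cilp) in sham muscle and 1 higher (Procr) for the interaction. limma voom called 0 higher in overloaded and 1 higher (Cilp) in sham muscle. Thinned counts gave 0 and 1 for cdKO in overloaded muscle, 0 lower in sham (233 genes at an unadjusted p under 0.05) and 1 higher (Procr) for the interaction. A fit to only the groups compared gave 0 and 1 in overloaded and 1 higher (Cilp) in sham muscle. With the satellite covariate overload in control had 533 higher and 574 lower, and with the Y-linked covariate 247 and 376. With the Y-linked covariate cdKO in overloaded muscle had 0 higher and 2 lower genes, Wwtr1 and Mid1. F2rl1 went from -1.68 ± 0.29 to -1.77 ± 0.44 and Cxcl13 from 2.58 ± 0.47 to 2.21 ± 0.69, so their calls ended with a larger SE more than with a smaller change. Without the 2 doubted libraries overload in control had 328 and 384, and cdKO lowered 1 gene in overloaded and 0 in sham muscle (306 at an unadjusted p under 0.05). Except where fewer genes or libraries were tested, the cause was not tested.

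Yap1 passed for overload in control with voom (-1.03) and with the replicate block (-0.79), and was at -0.15 with the Y-linked covariate. It lost its call for overload in cdKO with no filter (-0.93), DESeq2 (-0.96), thinned counts (-1.12) and without the 2 doubted libraries (-0.97). Wwtr1 in sham muscle lost its call with thinned counts (-1.62) and without the 2 doubted libraries (-1.71). With 1 library left out, genes higher by overload in control ran from 556 (without control overload replicate 2) to 1259 (without control overload replicate 1), and genes lower from 504 to 1249 without the same libraries. For overload in cdKO they ran from 210 to 666 and from 213 to 681, both lowest without cdKO overload replicate 3. For cdKO in overloaded muscle they ran from 0 to 17 and from 1 to 17, both highest without control overload replicate 1, in sham muscle lower genes from 0 to 1, and for the interaction higher genes from 0 to 1 (Procr). Yap1 ran from -1.10 to -0.52 for overload in control and from -1.18 to -0.76 in cdKO, and Wwtr1 from -1.88 to -1.62 in sham muscle.

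The replicate numbers are shared between groups, but same-numbered libraries had a mean correlation of deviations of 0.037, over 0.1 in 6 of 18 pairs, and 1 of 12 libraries correlated best with its own number, so they were not treated as pairs. The block gave 1752, 1035, 3, 1 and 0 calls in the 5 comparisons. Among list tests the block ended the calls of the erythroid list for overload in cdKO (adjusted p = 0.0684) and of cytokines in the interaction (adjusted p = 0.0717) and changed no other list call.

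The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For overload in control the real split gave 1768 genes and the highest other 1, and for overload in cdKO 1065 and 0, so 1 of 10 splits gave as many in each. In overloaded muscle cdKO gave 3 and the highest other split 7 (2 of 10 gave as many), and in sham muscle 1 and 0 (1 of 10). For the interaction the real labels gave 0 genes, so all 100 splits drawn, the real one included, had to give as many and the count decides nothing (the highest other gave 6).

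All 81 list calls were lost with a correlation estimated from the residuals (adjusted p given). For overload in control the estimate gave 0.0877 for matrix assembly, 0.153 for actin, tenogenic and interferon, 0.173 for class I and identity and 0.197 for G2/M, collagens, complement and ribosome biogenesis. It gave 0.232 for secreted signals, 0.247 for unfolded protein, 0.258 for pericyte and 0.260 for S phase and immediate early. It gave 0.310 for adipogenic, 0.458 for glycolysis, 0.471 for cytokines and 0.487 for respiratory chain. It gave 0.503 for basement membrane, 0.552 for endothelial and 0.658 for ribosomal protein. For overload in cdKO the estimate gave 0.0770 for matrix assembly, 0.153 for actin, identity, tenogenic, chondrogenic and interferon, 0.197 for collagens, secreted signals and class I and 0.208 for cytokines. It gave 0.232 for ribosome biogenesis, 0.258 for unfolded protein and pericyte, 0.268 for immediate early and 0.310 for complement. It gave 0.458 for G2/M, 0.462 for respiratory chain and endothelial, 0.468 for basement membrane and 0.486 for S phase. It gave 0.487 for ribosomal protein and erythroid and 0.503 for adipogenic. For cdKO in overloaded muscle the estimate gave 0.153 for G2/M and chondrogenic, 0.185 for S phase, 0.187 for sex-linked and 0.197 for complement, ribosome biogenesis and erythroid. It gave 0.232 for actin, 0.247 for sterol, 0.263 for Hippo and 0.455 for collagens. It gave 0.458 for glycolysis, 0.528 for basement membrane and 0.625 for unfolded protein. For cdKO in sham muscle the estimate gave 0.173 for chondrogenic, 0.197 for collagens and tenogenic, 0.221 for matrix-degrading and 0.232 for mitochondrial genome and erythroid. It gave 0.264 for interferon, 0.487 for ribosome biogenesis, 0.528 for ribosomal protein and 0.552 for basement membrane. For the interaction the estimate gave 0.153 for erythroid, 0.187 for sex-linked, 0.197 for matrix-degrading and 0.247 for complement. It gave 0.260 for G2/M, 0.310 for mitochondrial genome, 0.323 for class I and 0.458 for actin. It gave 0.487 for S phase, 0.528 for interferon and glycolysis and 0.593 for cytokines.

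fry ended 46 list calls (adjusted p given). fry for overload in control gave 0.0640 for glycolysis and respiratory chain, 0.0787 for cytokines, 0.154 for endothelial and 0.294 for ribosomal protein. fry for overload in cdKO gave 0.0541 for basement membrane, 0.0787 for respiratory chain, 0.0868 for S phase and 0.0922 for G2/M. It gave 0.0938 for erythroid, 0.113 for ribosomal protein, 0.122 for adipogenic and 0.131 for endothelial. fry for cdKO in overloaded muscle gave 0.0566 for sex-linked, 0.0600 for S phase, 0.0831 for ribosome biogenesis and 0.0934 for complement. It gave 0.108 for erythroid, 0.132 for Hippo, 0.140 for actin and 0.141 for collagens. It gave 0.161 for sterol, 0.321 for basement membrane, 0.373 for glycolysis and 0.608 for unfolded protein. fry for cdKO in sham muscle gave 0.0593 for collagens, 0.116 for mitochondrial genome, 0.161 for erythroid and 0.167 for matrix-degrading. It gave 0.171 for tenogenic, 0.260 for interferon, 0.459 for ribosome biogenesis and 0.481 for basement membrane. It gave 0.540 for ribosomal protein. fry for the interaction gave 0.0600 for erythroid, 0.0739 for sex-linked, 0.0930 for matrix-degrading and 0.154 for complement. It gave 0.181 for mitochondrial genome, 0.190 for class I, 0.209 for G2/M and 0.377 for actin. It gave 0.435 for S phase, 0.474 for interferon and 0.540 for cytokines and glycolysis. It passed chondrogenic for overload in control (0.00225), which camera did not.

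The satellite covariate ended 7 list calls (adjusted p given). Under it, overload in control had 0.160 for ribosomal protein and 0.248 for endothelial. Under it, cdKO in overloaded muscle had 0.163 for glycolysis and 0.331 for unfolded protein. Under it, the interaction had 0.0656 for interferon, 0.0696 for actin and 0.295 for glycolysis. It brought 4 lists under the threshold. Now overload in control had 0.0347 for erythroid. Now cdKO in overloaded muscle had 0.0267 for endothelial. Now the interaction had 7.43e-04 for ribosomal protein and 0.0428 for endothelial.

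Leaving out the 2 doubted libraries ended 10 list calls (adjusted p given). Without them, overload in control had 0.129 for endothelial. Without them, cdKO in overloaded muscle had 0.555 for unfolded protein and 0.705 for glycolysis. Without them, cdKO in sham muscle had 0.0629 for tenogenic, 0.0631 for matrix-degrading and 0.0730 for chondrogenic. Without them, the interaction had 0.0916 for interferon, 0.0992 for class I, 0.258 for actin and 0.676 for glycolysis. It brought 4 lists under the threshold. Here overload in control had 0.0142 for erythroid. Here cdKO in overloaded muscle had 0.00300 for endothelial. Here the interaction had 0.00361 for ribosomal protein and 0.0350 for endothelial.

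The Y-linked covariate ended 21 list calls (adjusted p given). With it, overload in control had 0.0576 for respiratory chain, 0.189 for adipogenic and pericyte, 0.410 for endothelial and 0.980 for ribosomal protein. With it, cdKO in overloaded muscle had 0.0570 for basement membrane, 0.194 for Hippo, 0.242 for actin, 0.344 for glycolysis, 0.427 for unfolded protein, 0.524 for collagens and 0.741 for sex-linked. With it, cdKO in sham muscle had 0.0743 for matrix-degrading. With it, the interaction had 0.122 for complement, 0.429 for matrix-degrading, 0.509 for glycolysis, 0.582 for S phase, 0.609 for actin, 0.674 for sex-linked, 0.702 for class I and 0.943 for cytokines. It brought 13 lists under the threshold. Then overload in control had 0.0120 for erythroid, 0.0205 for sterol and 0.0466 for chondrogenic. Then cdKO in overloaded muscle had 4.67e-05 for ribosomal protein, 7.33e-05 for endothelial, 0.00984 for heat shock, 0.0128 for adipogenic and 0.0228 for respiratory chain. Then the interaction had 1.92e-11 for ribosomal protein, 1.92e-04 for endothelial, 0.0135 for respiratory chain, 0.0181 for sterol and 0.0202 for heat shock.

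With each library left out in turn, 1911 list values kept their side of the threshold, 66 lost it and 63 gained it, in 52 pairs of list and comparison. The lowest and highest adjusted p of each pair follow, with the library behind the value that changed the call. Ranges for overload in control were 0.0207 to 0.130 for chondrogenic (lowest without control overload 3), 0.00100 to 0.128 for endothelial (highest without control overload 2) and 0.00949 to 0.311 for erythroid (lowest without control overload 2). They were 0.0299 to 0.208 for mitochondrial genome (lowest without control overload 1), 0.0263 to 0.138 for sterol (lowest without control overload 3) and 8.14e-04 to 0.0826 for tenogenic (highest without control overload 1). Ranges for overload in cdKO were 0.0478 to 0.151 for Schwann (lowest without cdKO overload 3), 0.00159 to 0.0710 for adipogenic (highest without cdKO sham 1) and 2.02e-04 to 0.0856 for erythroid (highest without cdKO sham 2). They were 0.0304 to 0.201 for glycolysis (lowest without cdKO overload 2). Ranges for cdKO in overloaded muscle were 8.87e-04 to 0.754 for identity (lowest without cdKO overload 1), 0.00553 to 0.233 for Hippo (highest without cdKO overload 3) and 0.0317 to 0.667 for TGF-beta (lowest without cdKO overload 2). They were 0.00457 to 0.9002 for adipogenic (lowest without control overload 1), 0.0362 to 0.573 for class I (lowest without control overload 1) and 5.74e-04 to 0.610 for basement membrane (highest without cdKO overload 2). They were 1.29e-04 to 0.916 for cytokines (lowest without cdKO overload 2), 2.88e-05 to 0.965 for ribosomal protein (lowest without control overload 1) and 0.00265 to 0.929 for endothelial (lowest without control overload 2). They were 0.00945 to 0.479 for collagens (highest without control overload 3), 1.71e-05 to 0.480 for glycolysis (highest without control overload 2) and 0.00650 to 0.9002 for immediate early (lowest without cdKO overload 1). They were 0.0179 to 0.918 for interferon (lowest without cdKO overload 2), 8.74e-04 to 0.993 for respiratory chain (lowest without control overload 1) and 0.00814 to 0.610 for tenogenic (lowest without control overload 1). They were 2.28e-04 to 0.964 for unfolded protein (highest without cdKO overload 2). Ranges for cdKO in sham muscle were 0.00103 to 0.141 for basement membrane (highest without cdKO sham 2), 0.0282 to 0.910 for G2/M (lowest without control sham 2) and 0.00959 to 0.0593 for chondrogenic (highest without control sham 3). They were 0.0207 to 0.865 for cytokines (lowest without cdKO sham 1), 8.75e-13 to 0.189 for ribosomal protein (highest without control sham 2) and 0.0367 to 0.827 for immediate early (lowest without control sham 1). They were 0.0114 to 0.274 for matrix-degrading (highest without cdKO sham 2), 0.0112 to 0.382 for ribosome biogenesis (highest without cdKO sham 2) and 3.33e-04 to 0.266 for tenogenic (highest without control sham 2). Ranges for the interaction were 0.00826 to 0.772 for identity (lowest without cdKO overload 1), 4.86e-04 to 0.134 for actin (highest without control overload 2) and 0.00127 to 0.397 for adipogenic (lowest without control overload 1). They were 0.00956 to 0.157 for class I (highest without cdKO overload 3), 2.56e-05 to 0.0612 for S phase (highest without control overload 2) and 7.61e-05 to 0.663 for cytokines (highest without cdKO overload 3). They were 1.89e-04 to 0.996 for ribosomal protein (lowest without cdKO sham 2), 0.0249 to 0.929 for endothelial (lowest without control overload 2) and 9.19e-04 to 0.506 for glycolysis (highest without control overload 2). They were 0.00433 to 0.772 for immediate early (lowest without cdKO overload 1), 2.71e-04 to 0.785 for interferon (highest without cdKO overload 2) and 0.00521 to 0.107 for matrix-degrading (highest without cdKO sham 2). They were 2.16e-04 to 0.0528 for mitochondrial genome (highest without cdKO overload 2), 0.0115 to 0.969 for respiratory chain (lowest without control overload 1) and 0.0298 to 0.656 for ribosome biogenesis (lowest without control overload 1). They were 4.33e-04 to 0.296 for sterol (lowest without cdKO sham 2) and 0.00157 to 0.909 for unfolded protein (lowest without control overload 1).

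Of the 81 list calls, 50 held in all 15 settings with 1 library or 2 left out or a covariate. These were 16 of 22 for overload in control, 21 of 23 in cdKO, 7 of 14 for cdKO in overloaded muscle, 4 of 10 in sham muscle and 2 of 12 for the interaction. The other scalings turned the median of 4 lists, none of which passed. Where libraries or genes were not left out, the cause of these changes was not tested. A floor of 3 counts is 1.95 to 9.72 CPM by library, which limits what genes at or below that level can show.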

Other observations

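The fit with the Y-linked share as a covariate was chosen after the data were seen.

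Overload also changed genes of signalling and stress lists that did not pass as lists. In the TGF-beta response, 5 rose, 4 fell and 11 did not pass of 20 in control (5 and 4 adjusted over the list alone, camera adjusted p = 0.854), and 4 rose, 4 fell and 12 did not pass in cdKO (4 and 4, camera adjusted p = 0.331). The feedback inhibitor gene Pmepa1 rose in both genotypes (1.36 ± 0.24 in control and 1.05 ± 0.24 in cdKO), while Tgfbi, a secreted adhesion protein (-1.83 ± 0.25 and -0.96 ± 0.25), and Id3, an inhibitor of differentiation factors (-2.32 ± 0.34 and -1.81 ± 0.34), fell. In control the list's median was -0.21 and its mean 0.19, with camera downward. Among heat shock genes, 3 rose, 5 fell and 7 did not pass of 15 in control (3 and 7 adjusted over the list alone, camera adjusted p = 0.690), and 1 rose, 2 fell and 12 did not pass in cdKO (1 and 3, camera adjusted p = 0.611). The mitochondrial co-chaperone gene Hspe1 rose (1.495 ± 0.28 and 1.54 ± 0.28), whereas the cytosolic co-chaperone gene Dnajb1 fell (-1.24 ± 0.28 and -1.41 ± 0.28). For sterol biosynthesis, 4 rose, 1 fell and 10 did not pass of 15 in control (6 and 1 adjusted over the list alone, camera adjusted p = 0.118), and 1 rose, 0 fell and 14 did not pass in cdKO (0 and 0, camera adjusted p = 0.500). Cyp51, a demethylase of the pathway, rose in both (1.18 ± 0.31 and 0.90 ± 0.30).

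Control overload replicate 1 and cdKO overload replicate 2 lay nearer to the sham libraries than the other overloaded libraries, at 15.8 and 7.39 on the first principal component (46.4% of the variance) against 32.6 to 61.1, with sham libraries from -39.9 to -28.7. Background that dilutes every change was argued against: genes of at least 200 CPM called in the other genotype, which a small background would leave almost whole, kept only 0.696 and 0.636 of the change of the other overloaded libraries. Cells that did not respond, mixed with cells that did, would shrink the log2 change of lowered genes more than that of raised genes. The share kept by lowered genes minus that kept by raised genes was -0.212 ± 0.081 and -0.150 ± 0.077 (SE over genes). Only the first lay beyond the bound, a share lower by 0.1, by more than 1 SE, so this mixture cannot be told apart from an even loss. A lower response of the animals or muscles behind these libraries was not tested.

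The pools may differ in the sex of their cells. Xist was at 2.89 and 3.15 CPM in cdKO overload replicates 1 and 3 and at 20.8 to 200 CPM in the other 10 libraries, while Y-linked genes had counts in all 12, so most libraries held RNA from both sexes, or reads that the counting gave to both. With the Y-linked covariate overload in control raised 247 genes and lowered 376.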
